A study of Mus musculus with 6 samples.

How the data were processed

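RNA of gastrocnemius muscle, a calf muscle, was measured on 6 Affymetrix expression arrays, 1 per mouse. Per the labels, 3 mice carried a floxed TAK1 gene without deletion and served as controls, and 3 littermates had TAK1 deleted in skeletal muscle for 3 weeks. TAK1 is the kinase encoded by Map3k7. Per the labels' protocols, total RNA was extracted with Trizol and converted to biotin-labelled cRNA.

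The deposited values were log2 probe set summaries, with 41345 probe sets per array. Per the submitters' processing notes, RMA, oligo and limma were used, and their versions and order are not given in the sources used here. RMA is a method that subtracts background, makes the arrays' intensity distributions alike and combines the probes of a probe set on a log2 scale. The step compresses differences of dim transcripts, so fold changes near background can be too small. Scanner files, detection calls and scan dates were not used here, so batches of scanning were not tested. The number of arrays limits the precision of every value.

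Genes were named through GEO's platform annotation, which can be old. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had none. Entrez identifiers of 23328 single-symbol probe sets were found in the mouse RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table was used for names only. The labels and the deposited table name no genome build for the arrays, so no coordinates are printed. A gene with several probe sets (1082 genes) was represented by the probe set with the highest mean over all 6 arrays, which left 22180 genes. Probe sets with several symbols or none were tested only in an alternative. On all 6 arrays, 1397 probe sets held the same values as another probe set.

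Knockout and control muscle were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with default settings, group means only, two-sided tests and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05. No filter on dim genes was applied. As a guide to background, the 95th percentile of the means of 1394 olfactory and vomeronasal receptor genes was taken, which was 5.85 on the log2 scale, and 12601 genes (56.8%) lay above it. This background was chosen after seeing the data and decided no call. Where only the lower group of a called gene lay below it, the fold is given as at least that of the higher group over this level, and where both did, no fold is given. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists with at least 5 measured members. Beside it stand camera with an estimated correlation, which allows for members that vary together, and fry, which tests whether a list's genes move one way without comparing them with other genes. For Map3k7 a two-sided exact permutation test of 3 against 3 arrays was added. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

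The tests, 39 gene lists, alternatives and rule for named genes were fixed before the data were examined. Of 1012 list entries, 927 were measured, and 38 lists were tested, since the list of red blood cell markers had too few measured members. The rule named Map3k7, up to 12 called genes with the largest change in each direction whose knockout values all lay beyond all control values (leaving out predicted genes and clone names), up to 4 called members of each list, and 14 fixed genes whatever their test gave. Of those 14 genes, 12 were measured on a probe set of their own. Gadd45a shared its probe set with another gene, and Gdf15 had no probe set with a single symbol, so neither is reported. Other list members named as examples were chosen after their values were seen: those past an adjusted p of 0.05 over the list alone, or otherwise members with large changes. Adjustment over the list alone does not allow for the number of lists, so a pass there is weaker than a pass over all genes.

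The gene test was tested on simulated data with 22180 genes, of which 200 were changed, in 10 simulations of 3 against 3 arrays. It recovered 53.0% of genes changed 1.5-fold, 97.8% of those changed 2-fold and 99.7% of those changed 4-fold, and 6.45% of its calls were false. With independent genes, the list test recovered 10 of 10 lists shifted by 0.2 on the log2 scale and called 1 of 370 unshifted lists. The simulation holds no inter-gene correlation, so it says nothing of lists whose members vary together. It used normal noise at limma's moderated variances, which share information between genes, and a set number of changed genes. The recovered shares therefore need not hold for these arrays. In the main test (limma), some genes that differed over 2-fold were not called. Map3k7cl was 3.18-fold lower (adjusted p = 0.0511) and Fam174b 3.00-fold higher (adjusted p = 0.0928).

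Alternatives were quantile normalization, median centring, the mean over probe sets, a test of every probe set, filters on dim genes, an intensity trend with a robust prior, array weights, the replicate number as a block, leaving out each array, a plain per-gene test of means, other thresholds, the other list tests, and lists without shared members. The filter at the receptor-gene level was added after seeing the data.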

Results

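Gene expression was compared between gastrocnemius muscle of 3 floxed control mice and of 3 littermates with a muscle-specific knockout of TAK1, 3 weeks after deletion. TAK1 is a kinase that relays cytokine and TGF-beta family signals to the NF-kB and MAP kinase pathways. The arrays had median log2 levels between 5.78 and 5.84. Across genes, which are not independent replicates, Pearson's r between arrays was 0.990 to 0.992 within groups and 0.985 to 0.990 between groups. The first principal component held 31.1% of the variance and placed the 3 knockout arrays (6.12 to 24.4) apart from the 3 control arrays (−24.9 to −1.01). The second held 20.7%.

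Map3k7 is the targeted gene. Its level was 8.40 ± 0.07 in control and 8.22 ± 0.06 in knockout muscle on the log2 scale (SD, n = 3), with probe set 17412350. All 3 knockout values lay below all 3 control values, and the mean was 12.1% lower (log2 fold change −0.19, 95% confidence interval −0.40 to 0.03). The difference did not pass the test over all genes (limma, adjusted p = 0.686), and the exact permutation test gave a two-sided p of 0.1, the smallest that 3 against 3 arrays can give. The labels do not say which exons were deleted, and cells other than muscle fibres keep the gene, so this level does not settle whether the labels hold.

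The comparison of all genes asked which transcripts differ between muscle labelled as TAK1 knockout and control muscle. Sarcolipin (Sln), a small inhibitor of the calcium pump of the sarcoplasmic reticulum, had the largest rise among called genes. Its log2 level was 8.21 ± 1.11 in control and 12.57 ± 0.33 in knockout muscle (SD, n = 3), a 20.5-fold difference (log2 fold change 4.36, SE 0.47, adjusted p = 0.0304). Without control 3, which had the lowest level, the log2 fold change was 3.72 (adjusted p = 0.00156). The call was lost without control 1 (adjusted p = 0.0595), knockout 1 (0.0849), knockout 2 (0.119) or knockout 3 (0.0552), and with an intensity trend and robust prior (0.0740). The alpha subunit of the muscle acetylcholine receptor, Chrna1, rose 3.00-fold, from 8.66 ± 0.10 to 10.25 ± 0.18 (log2 fold change 1.58, SE 0.12, adjusted p = 0.00565). Esr1, the estrogen receptor alpha, rose 2.65-fold (log2 fold change 1.40, SE 0.14, adjusted p = 0.0298), with 1 probe set covering the gene. Fibro-adipogenic and adipocyte markers had median log2 fold changes of −0.17 and −0.11 on the same arrays. Chrna9, another nicotinic receptor subunit, rose 2.20-fold and Car2, a carbonic anhydrase, 2.13-fold. Klhl40, a protein that stabilises the thin filament, rose 1.96-fold, the lysosomal protease legumain (Lgmn) 1.88-fold, Atp1b4, a muscle relative of sodium pump beta subunits, 1.87-fold and Tns3, an adhesion protein, 1.71-fold. Adjusted p for these 6 genes lay between 0.0327 and 0.0497.

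Flrt1, a transmembrane protein with leucine-rich repeats, had the largest fall among called genes. It was 9.84-fold lower in knockout muscle, at 7.02 ± 0.35 against 10.32 ± 0.41 (SD, n = 3; log2 fold change −3.30, SE 0.23, adjusted p = 0.00565). Tceal7 was at least 5.05-fold lower, since its knockout mean of 5.47 lay below the 5.85 taken as background (measured log2 fold change −2.72, SE 0.24, adjusted p = 0.00971). Mss51, a mitochondrial protein of skeletal muscle, was at least 5.50-fold lower, with a knockout mean of 5.69 below background and a control SD of 0.81 (measured log2 fold change −2.62, SE 0.34, adjusted p = 0.0428, or 0.0542 with an intensity trend and robust prior). The tetraspanin Tspan8 was 3.19-fold lower and Aldh1a1, an enzyme that makes retinoic acid, 2.94-fold lower. Dhrs7c, an oxidoreductase of the sarcoplasmic reticulum, was 2.56-fold lower and Asb15, a substrate adaptor of ubiquitin ligases, 2.53-fold lower. Neu2, a cytosolic sialidase, had a log2 fold change of −1.23 (adjusted p = 0.00971), with both group means (5.52 and 4.28) below background. Osbpl6, a lipid transfer protein, was 2.11-fold lower and Cacng7, a calcium channel subunit, 1.77-fold lower. The transcripts Gm4544 and 2310020H05Rik fell as well, by 1.59 and 0.89 on the log2 scale, and were named after their values were seen.

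**Figure D1:**
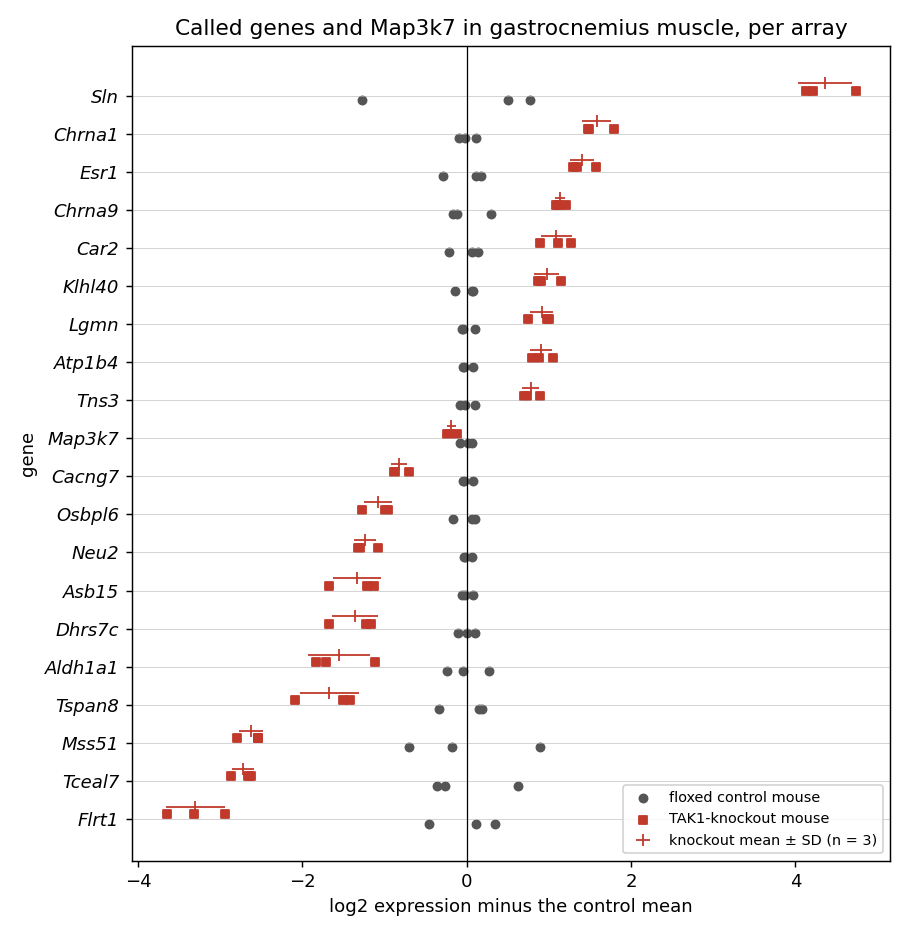
Log2 expression per mouse relative to the control mean (x axis) for the named called genes and Map3k7 (y axis), with grey circles for the 3 control mice, red squares for the 3 knockout mice and crosses for the knockout mean ± SD. Knockout values of every gene shown lay beyond all its control values, which the naming rule required for all but Map3k7. The widest control spread was that of Sln (SD 1.11).

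In all, 21 of 22180 genes passed an adjusted p of 0.05, 9 higher and 12 lower in knockout muscle, and in all 21 the groups did not overlap. Groups did not overlap in 2968 genes (13.4%), where chance gives 10%. An unadjusted p of 0.05 was passed by 1784 genes, against 1109 expected by chance. In other splits of the 6 arrays, which mix the groups, this count ran from 624 to 1566. Without 1 array the count was 7 for each of controls 1, 2 and 3, and 3, 2 and 11 for knockouts 1, 2 and 3, and of the 19 named called genes only Chrna1 and Flrt1 passed in all 6 of these fits. A per-gene test that does not share variance between genes called 0 genes (1612 at unadjusted p under 0.05), and a test of every probe set called 6.

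Genes of the neuromuscular junction and the denervation response were the only fixed group with called members. Of 27 measured, 2 rose over all genes (Sln and Chrna1), 0 fell and 25 did not pass. Adjusted over the list alone, 7 rose and 3 fell. The others that rose were the receptor subunits Chrnb1 (log2 fold change 0.77) and Chrnd (0.41), the synaptic kinase Musk (0.75), the potassium channel Kcnn3 (0.71) and utrophin, Utrn (0.33). Those that fell were embryonic myosin Myh3 (−0.84), the sodium channel subunit Scn3b (−0.64) and Ankrd1 (−1.17). Myogenin, Myog, a transcription factor that denervation induces, had a log2 fold change of 0.17 (adjusted p = 0.855). In all, 15 members were higher and 12 lower, with a median shift of 0.17 (camera, adjusted p = 0.0178; adjusted p = 0.744 with an estimated correlation). The quartiles were −0.12 and 0.33, while the mean of 0.23 included Sln (4.36) and Chrna1 (1.58). Whether the list shifts without these 2 genes was not tested. The call was lost without control 3 (adjusted p = 0.111), knockout 1 (0.0844) or knockout 3 (0.0549), and with the mean over each gene's probe sets the median was 0.08 (0.0230).

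**Figure D2:**
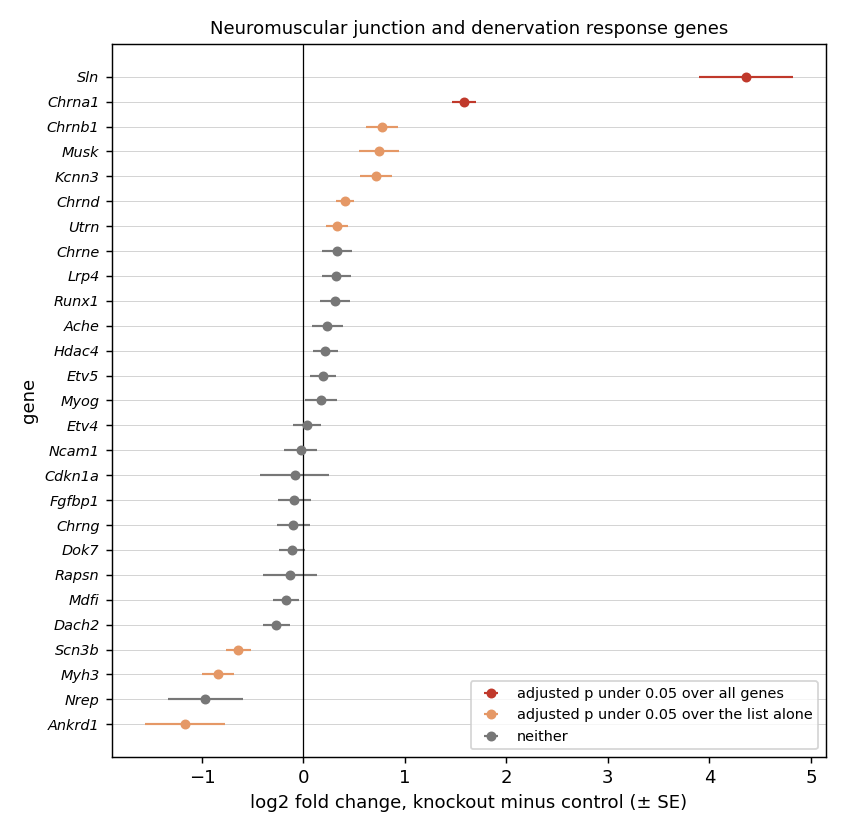
Log2 fold change of knockout over control ± SE (x axis) for the 27 measured neuromuscular junction and denervation genes (y axis), coloured by whether they passed over all genes, over the list alone or neither. Sln (4.36) and Chrna1 (1.58) passed over all genes.

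Genes of mitochondrial energy metabolism lay slightly higher as groups, with 0 members called over all genes. Of 53 oxidative phosphorylation genes, 47 were higher, with a median log2 fold change of 0.10 (camera, adjusted p = 0.00242; adjusted p = 0.894 with an estimated correlation). Of 28 genes of fatty acid uptake and oxidation, 25 were higher, with a median of 0.13 (adjusted p = 0.00242; adjusted p = 0.820 with an estimated correlation). Of 19 tricarboxylic acid cycle genes, 17 were higher, with a median of 0.11 (adjusted p = 0.0155; adjusted p = 0.820 with an estimated correlation). Adjusted over the list alone, 0 members of the first 2 lists passed, and in the cycle list Pcx, which feeds the cycle with oxaloacetate, fell by 1.06 on the log2 scale. Ppargc1a, a coactivator of mitochondrial genes, was 1.51-fold higher without passing (adjusted p = 0.351), and the list of mitochondrial biogenesis genes had a median of 0.04 (adjusted p = 0.228). Control 1 had the lowest oxidative phosphorylation median of the 6 arrays, and without it the 3 lists had adjusted p of 0.998, 0.352 and 0.525, with an oxidative phosphorylation median of −0.0002. The oxidative phosphorylation call was also lost without knockout 2 (adjusted p = 0.0537) and the cycle call without knockout 1 (0.0940).

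Genes of 2 signalling lists lay slightly lower. Of 39 genes of myostatin, activin and BMP signalling, 30 were lower, with a median of −0.07 (camera, adjusted p = 0.00242; adjusted p = 0.744 with an estimated correlation). None passed over all genes, and adjusted over the list alone 2 fell, the signal transducer Smad3 (log2 fold change −0.69) and the ligand Gdf11 (−0.56). The call held without any 1 array, with a median of −0.04 without control 1 and −0.11 without knockout 1. Of 32 MAP kinase and immediate early genes, 24 were lower, with a median of −0.09 (adjusted p = 0.0155; adjusted p = 0.744 with an estimated correlation). Adjusted over the list alone, the phosphatase Dusp8 (−0.76) and the p38 kinase Mapk14 (−0.47) fell. This call was lost without control 1 (adjusted p = 0.116), control 3 (0.0884), knockout 1 (0.0541) or knockout 2 (0.0537), and with above-median genes (0.101) or genes above the receptor-gene level (0.0819) only. Targets of NF-kB and inflammatory cytokines had a median of −0.004 (adjusted p = 0.933), with 0 of 37 called and 0 over the list alone. Only 23 of the 37 lay above background, and differences of the others are limited by the low signal.

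Lists of protein breakdown genes did not pass as groups (camera). Atrophy ubiquitin ligases had a median of −0.004 (adjusted p = 0.982), and their best known members, Fbxo32 and Trim63, had log2 fold changes of 0.15 and −0.01 (adjusted p = 0.885 and 0.998). Adjusted over the list alone, 1 of 17 ligase genes rose, Cblb (0.53). Of 36 proteasome subunits, 27 were lower, with a median of −0.05 (adjusted p = 0.111). Autophagy and lysosome genes had a median of 0.01 (adjusted p = 0.463), and adjusted over the list alone Gabarapl1 rose (0.87) and Map1lc3a fell (−0.48). The autophagy genes Sqstm1 and Map1lc3b had log2 fold changes of 0.08 and −0.001 (adjusted p = 0.951 and 0.999).

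Of 30 endoplasmic reticulum stress genes, 25 were higher, with a median of 0.06 (camera, adjusted p = 0.0352; adjusted p = 0.820 with an estimated correlation). Adjusted over the list alone 1 rose, the stress transcription factor Atf3 (0.97), while the chaperone Hspa5 had a log2 fold change of 0.06 (adjusted p = 0.944). Of 28 genes of the translation apparatus, 20 were higher, with a median of 0.10 (adjusted p = 0.0098; adjusted p = 0.820 with an estimated correlation) and 0 called over all genes or over the list alone. The stress call was lost without control 2 (adjusted p = 0.476), knockout 1 (0.0586) or knockout 3 (0.131), and the translation call without control 2 (0.252) or knockout 3 (0.222). The stress call was also lost with the mean over probe sets (0.0603) and with array weights (0.0554). The hormone Fgf21 (0.11, adjusted p = 0.839) lay below background, and the antioxidant enzyme Nqo1 had a log2 fold change of −0.35 (adjusted p = 0.589).

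Fast fibre proteins had a median of −0.03 over 20 genes, 14 of them lower (camera, adjusted p = 0.0418; adjusted p = 0.820 with an estimated correlation). Adjusted over the list alone, the light chain Mylpf (−0.46) and its kinase Mylk2 (−0.50) fell, and 0 passed over all genes. The call was lost without control 2 (adjusted p = 0.0534), control 3 (0.166), knockout 2 (0.163) or knockout 3 (0.0549). With all arrays it was lost under quantile normalization (adjusted p = 0.0683), with above-median genes only (0.101) and with genes above the receptor-gene level only (0.0969), and the median was −0.04 with the mean over probe sets or with every probe set tested. The myosin heavy chains Myh4 of fast and Myh7 of slow fibres had log2 fold changes of −0.003 and 0.06 (adjusted p = 0.998 and 0.986), and Myh4 lay at 14.15 and 14.14, near the arrays' highest values of 14.31 to 14.34, where a difference can be compressed. Slow fibre proteins had a median of 0.12 (adjusted p = 0.675). Circadian clock genes were lower in 15 of 17 cases, with a median of −0.11 (adjusted p = 0.0155; adjusted p = 0.744 with an estimated correlation) and 0 called over all genes or over the list alone. That call was lost without control 1 (adjusted p = 0.178) or control 3 (0.0503).

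Among markers of other cells, tendon markers lay lowest. All 11 were lower, with a median log2 fold change of −0.68 (camera, adjusted p = 1.6e-05; adjusted p = 0.744 with an estimated correlation), and 0 passed over all genes or over the list alone. The largest differences were in Kera (−1.43) and Tnmd (−1.02), a tendon membrane protein. Medians per array, relative to each gene's mean over all arrays without the gene shared with the matrix list, were 0.03, 0.54 and 0.31 in controls and 0.07, −0.35 and −0.95 in knockouts. The shift was −0.35 without knockout 3 (adjusted p = 0.00173) and −1.08 without knockout 1. Extracellular matrix genes had a median of −0.14 over 34 genes (adjusted p = 0.0447; adjusted p = 0.894 with an estimated correlation), with 0 called over all genes or over the list alone. Without knockout 3 their median was 0.002 (adjusted p = 0.296), and the call was also lost without control 2 (0.522) or control 3 (0.229). With all arrays it was lost under quantile normalization (adjusted p = 0.0786), with every probe set tested (0.0513), with above-median genes only (0.0568), without members shared between lists (0.0558) and with genes above the receptor-gene level only (0.0870). Neutrophil markers had a median of 0.13 (adjusted p = 0.0155; adjusted p = 0.762 with an estimated correlation), but only 2 of 13 lay above background, 0 passed over all genes or over the list alone, and the call was lost without control 3 (0.172) or knockout 3 (0.297). Macrophage markers had a median of 0.01 (adjusted p = 0.591).

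**Figure D3:**
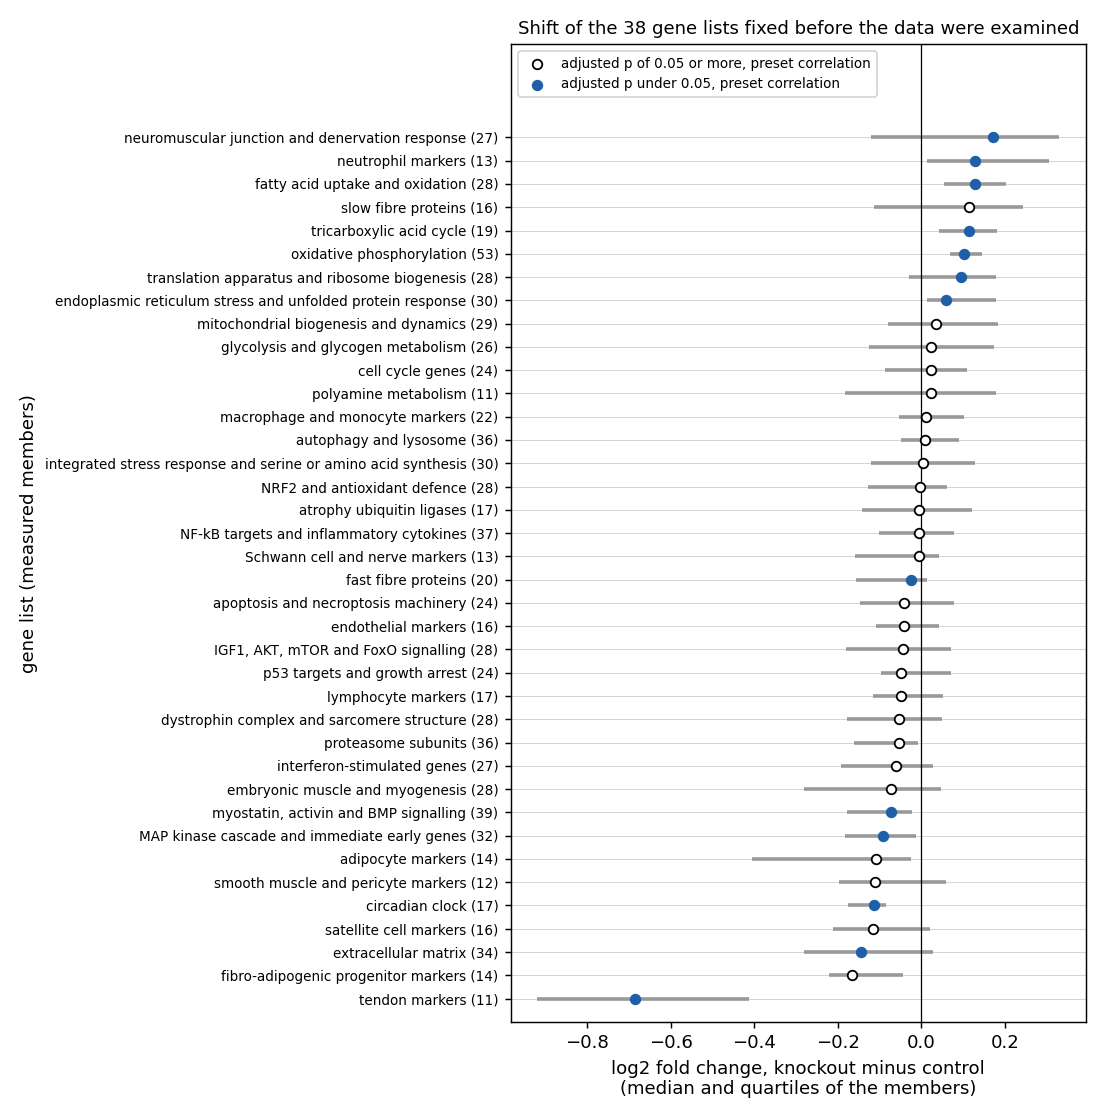
Median and quartiles of the members' log2 fold change, knockout minus control (x axis), for the 38 tested gene lists with their measured members in brackets (y axis), with blue points for an adjusted p under 0.05 at the preset correlation. Tendon markers lay lowest, at −0.68.

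At the preset correlation 13 of 38 lists passed, 7 higher and 6 lower. With an estimated correlation 0 passed (0 at an unadjusted p under 0.05), and by fry 0 passed (4 at an unadjusted p under 0.05). At the preset correlation, other splits of the 6 arrays, which mix the groups, gave 3 to 14 lists. The count of 13 alone therefore does not tie the shifts to the knockout. For each of the 13 lists, leaving out at least 1 of the arrays moved the median by over 1.5 times. Median, mean and test differed in sign for the integrated stress response, polyamine, NF-kB, p53, atrophy ligase and glycolysis lists, of which none was called.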

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

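The tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the arrays.

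Among probe sets without a gene name in the annotation, which enter no comparison of genes, 4 were far higher in every knockout array. Their log2 fold changes were 5.03, 4.73, 5.63 and 5.37 (26.6-fold to 49.7-fold), 2 of them for probe sets 17550683 and 17551165. Control values lay between 5.21 and 7.01 and knockout values between 10.8 and 11.8, with knockout SDs of at most 0.094.

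Of the other 16006 unnamed probe sets, 1 differed by over 2 on the log2 scale. RMA had made the arrays' intensity distributions alike before this count. The count therefore cannot test an array-wide difference in intensity as a source of these 4 probe sets. On these probe sets 0 arrays lay on the wrong side of the midpoint and the gap between the groups was at least 4.20, but both values restate the separation by which they were picked, so neither tests a swap of arrays nor favours a cause. A transcript that only the knockout mice carry, such as that of a recombinase transgene, a control RNA added unequally and a mouse transcript induced by the loss of TAK1 cannot be told apart, since the probe sets are unnamed here.

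Esr1 was 2.65-fold higher in knockout muscle. More connective tissue or fat cells are argued against as the whole source, because the upper quartile of log2 fold changes was at most −0.024 in both the fibro-adipogenic and the adipocyte marker list. A recombinase fused to part of the estrogen receptor could be read by the Esr1 probes. The gap of 1.12 between the lowest knockout and the highest control value cannot tell this from a change of the mouse gene, since 1 probe set covers the gene and the labels do not describe the recombinase. A change of Esr1 itself after TAK1 loss stays open and was not tested further.

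Tendon markers were lower in knockout muscle. Within groups, the arrays with lower tendon markers had lower extracellular matrix genes, without the shared gene (6 arrays, r = 0.97, rho = 0.94). Each had a one-sided exact permutation p of 0.0278, the smallest that 36 permutations can give. Without the 2 arrays farthest from the median r was 0.89. This was the only relation computed, so p was not adjusted. The pair of lists was chosen after the results were seen, and p does not allow for that choice. A relation within groups cannot say why the groups differ. Knockout 1 had the highest matrix median of the 6 arrays (0.22), with a tendon median of 0.07. Knockout 3 had the lowest of both (−0.44 and −0.95). Different amounts of tendon and connective tissue in the dissected pieces stay open. So does a difference in tendon gene expression after TAK1 loss, which was not tested.

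For the 21 called genes, 1 of the 10 splits of the 6 arrays, the real split, gave as many, and the highest other split gave 1. For the 13 called lists, 2 of the 10 splits gave as many, the real split among them. The other splits gave 3 to 14 lists, so the count of lists does not set the real split apart. The 10 splits are too few for a share under 0.05.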

How the results depend on the processing

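The filter at the level of receptor genes was chosen after seeing the data, and all other settings were planned. Of 21 called genes, quantile normalization, median centring, probe set means and array weights gave 21, 23, 21 and 22. Fewer or more were called with every probe set tested (6, of which 4 were unnamed), above-median genes only (53, 20 of them shared), trend and robust prior (36, 19 shared), the receptor-gene filter (45, 20 shared), a plain per-gene test of means (0), and an unadjusted p of 0.05 with 1.5-fold (257). Filters test fewer genes, and the cause of the other differences was not tested. Leaving out an array gave 2 to 11 genes and 7 to 13 lists, with fewer arrays in each fit. Of 13 called lists, 0 passed with an estimated correlation and 0 by fry, and 9 to 14 passed under the settings that kept all arrays and the preset correlation. Map3k7 kept its direction and stayed uncalled under all 16 alternatives (−0.23 to −0.15 across left-out arrays). Both filters on dim genes left no value for Neu2, Fgf21 and neutrophil markers. Of the named called genes, 0 changed direction, and Chrna1 and Flrt1 lost their call only in the plain per-gene test.

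Uncalled genes near 0 changed sign. Array weights gave 0.015 for Trim63 and 0.016 for Map1lc3b. Across left-out arrays, log2 fold changes ran from −0.30 to 0.33 for Trim63, −0.16 to 0.22 for Map1lc3b, −0.015 to 0.0069 for Myh4, −0.0070 to 0.11 for Hspa5, −0.039 to 0.24 for Sqstm1 and −0.32 to 0.41 for Myh7. Without a change of sign they ran from 0.0077 to 0.31 for Fbxo32, 0.056 to 0.31 for Myog and −0.48 to −0.23 for Nqo1. Medians ran from −0.00025 to 0.17 for oxidative phosphorylation and from −0.32 to 0.0021 for extracellular matrix. The cause was not tested.

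With the replicate block, 17 genes were called, of which 12 were shared. Same-numbered arrays deviated from their group means with correlations of 0.08, 0.21 and −0.07, against −0.22 to 0.14 for different numbers. Of the 3 numbers, 1 correlated best with its own. So few arrays cannot exclude pairing. The labels do not say that the numbers pair the mice, so the block served as an alternative only. Of 22180 genes, 12601 lay above the level of receptor genes, and differences of the others are limited by the low signal.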

Other observations

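The genes described here were chosen after their values were seen.

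With genes below the median level left out, which leaves 11090 genes to test, 53 genes passed an adjusted p of 0.05 (limma), and 33 of them did not pass over all genes, 10 higher and 23 lower. Myoregulin (Mrln), a micropeptide that inhibits the calcium pump of the sarcoplasmic reticulum, was 2.30-fold lower (log2 fold change −1.20, SE 0.20, adjusted p = 0.0470). Slc8a3, a sodium-calcium exchanger, was 1.84-fold higher (adjusted p = 0.0370). The muscle protease Capn3 was 1.79-fold lower and Klhl31 1.48-fold lower (adjusted p = 0.0387 and 0.0470). Gyg, the primer protein of glycogen synthesis, was 1.71-fold lower (adjusted p = 0.0398).

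In the same fit, Map3k7cl, a gene named for its similarity to Map3k7, was 3.18-fold lower in knockout muscle (9.06 ± 0.50 against 7.39 ± 0.14, SD, n = 3), with an adjusted p of 0.0222 there and 0.0511 over all genes. The iron exporter Slc40a1 was 2.56-fold lower, Arhgap20 2.70-fold lower and Pkia, an inhibitor of protein kinase A, 1.87-fold lower. Fam174b was 3.00-fold higher, Ttc9 2.18-fold higher, the imprinted gene Peg3 1.93-fold higher and the flagellin receptor Tlr5 1.62-fold higher. Over all genes, adjusted p for these 7 genes lay between 0.0756 and 0.135.

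Some members of uncalled lists passed when adjusted over the list alone, without adjustment across lists. None of them passed over all genes. In the glycolysis and glycogen list 3 of 26 fell, Phka1 (−0.82), Gyg (−0.77) and the lactate carrier Slc16a3 (−0.59). In the embryonic muscle list Xirp1 (1.06) and Csrp3 (0.92) rose and Myh3 (−0.84) fell. In the antioxidant list Gpx3 (−0.80) and Me1 (−0.58) fell. In the list of p53 targets and growth arrest 1 of 24 rose, the cell cycle inhibitor Cdkn1c (0.55), and in the apoptosis and necroptosis list 1 of 24 fell, Capn3 (−0.84). Dystrophin, Dmd, fell by 0.55 in its list and Car3 by 0.63 in the slow fibre and adipocyte lists.

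The labels give no sex of the mice. On all 6 arrays Xist lay between 9.98 and 10.28, and the Y-linked genes Kdm5d, Eif2s3y and Uty lay between 3.12 and 3.85, under the 5.85 taken as background.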
